A study of Mus musculus with 2 samples.

How the data were processed

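Total RNA from lung of mouse embryos at embryonic day 14.5 (strain B6NCrl per the labels) was sequenced as 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. Per the labels, RNA was extracted with the Ambion mirVana kit, each library started from 10.0 ng of RNA with a size minimum of 200 nt, and spike-in RNA was added. One linked protocol is named for Smart-seq, a method that makes full-length cDNA from small amounts of RNA, and whether RNA without a poly(A) tail was captured is not given in the sources used here. The tissue was collected on day 15 of July for replicate 1 and day 17 for replicate 2. The labels describe each sample both as pooled male and female and as pup 1, so the number of animals behind a library is uncertain. The labels number the libraries as separate biological replicates, and any p-value below compares these 2 libraries only.

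For each library the authors deposited a gene table and a transcript table. Per the file headers, these hold an expected count, which is an estimated number of reads per feature that need not be whole, and TPM, an abundance unit which divides by effective length and scales each library to the same sum over all features, spike-ins included. The transcript tables also give, per the file headers, the percent of a gene's TPM carried by each transcript, and both tables give posterior mean TPM and posterior standard deviations of the count. The deposited read-me files name the mouse build mm10, GENCODE release M4 and transcriptome alignments as the source of the tables. The aligner, the quantification program and their versions are not given in the sources used here, nor is whether strand was used in counting, so overlapping and antisense genes may share reads.

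Each gene table held 69691 features: 43346 mouse genes, 96 ERCC spike-ins, 1 phiX entry and 26248 entries with a numeric identifier. The numeric entries were mostly under 100 nt, and 63 of them had an effective length above 0. In all 26303 features of 100 nt or more with 1 transcript, the effective length was the length minus 99 nt, so 2218 mouse genes shorter than 100 nt could take no reads and features just over that length have inflated TPM. Symbols, gene types and coordinates came from GENCODE M21 on GRCm38, the same build as mm10, by unversioned identifier, and 42462 of the 43346 mouse genes matched. Coordinates are 1-based. A newer release than M4 was used for names, so some transcript models differ between the 2 releases.

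Library sizes were the summed expected counts. For ratios, expected counts were rounded to whole numbers and scaled with TMM (edgeR 4.0.16, R 4.3.3) over the 14870 genes with mean TPM of 1 or more. Ratios are replicate 2 over replicate 1 on the log2 scale after adding 0.5 to each count. Each gene was tested with an exact two-sided binomial test of its 2 counts given their sum, with Benjamini-Hochberg adjustment over these genes, and was called where the adjusted p was under 0.05 and the ratio was at least 2-fold. This test compares 2 libraries, not conditions. Nothing in the sources used here mentions molecular identifiers, so all intervals and floors cover counting error only. The confidence level is 95%, shares carry exact (Clopper-Pearson) intervals, and a count of 0 allows up to 3 counts where reads are not shared with other copies, or 0.0939 CPM (counts scaled to the same total of mouse gene counts) in replicate 1 and 0.0905 in replicate 2. Agreement was measured on log2(TPM + 1), and the biological coefficient of variation came from edgeR's common dispersion with an intercept only.

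Before the data were examined, 47 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of the symbols in the lists, 9 were not matched. A member counts as detected at TPM 1 or more in both libraries. The median of a list's mean TPM was placed among 10000 random lists of the same size from all protein-coding genes. For lists with at least 5 members at mean TPM 1 or more, the median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins. These percentiles describe the 2 libraries and are not tests of a condition. Named genes were the 4 highest members of each list (3 for tissues other than lung), a fixed set of lung regulators, the 10 highest genes outside the mitochondrial genome and the spike-ins, the 10 called genes per direction with the largest ratio and a mean of at least 100 counts, all members of the Y-linked and X-inactivation list, and the 4 members furthest in the list's direction where a list's ratio fell outside the central 95% of random lists. Ribosomal protein and histone classes were taken by symbol. The exon pairs of the FGF receptors and Pkm were taken from the annotation after the data were examined.

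The test was checked on simulated counts drawn for 14870 genes from the means and sizes of these 2 libraries, with 200 genes changed. Of 14670 unchanged genes 1 was called, and 46 of 50 genes changed 2.5-fold, 48 of 50 changed 4-fold and 50 of 50 changed 8-fold were recovered, while 0 of 50 changed 1.5-fold were called, as the 2-fold limit requires. These simulated counts held counting noise only, without variation between libraries, so they do not give the rate of false calls in the real data. A simulated coefficient of variation of 10% was recovered as 10.1%. Among 400 unshifted random lists of 10 genes, 18 fell outside the central 95%, and 88 of 100 lists shifted by 0.3 on the log2 scale were found. Alternatives were other scalings (DESeq2 1.42.0 size factors, total count, spike-in sum), other filters, thresholds and pseudocounts, posterior mean values, TPM rescaled without spike-ins, mitochondrial genes and numeric entries, edgeR's exact test, and leaving out each replicate. Computation used Python 3.11.15 with pandas, numpy and scipy. The spike-in concentrations were not used here, and some single genes that the rule names are not reported here.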

Results

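Lung tissue of mouse embryos at embryonic day 14.5, the stage of branching growth before air sacs form, was profiled by RNA sequencing in 1 group of 2 libraries, biological replicates 1 and 2 per the labels. The labels name the material total RNA, and whether RNA without a poly(A) tail was captured is not given in the sources used here. The design holds no second condition, so the data answer which genes were expressed, at what level, and how far the 2 replicates differed. Summed expected counts were 33601136 in replicate 1 and 34535168 in replicate 2, of which 31940637 and 33167255 fell on mouse genes. Of the mouse gene counts, 94.4% and 94.5% lay on protein-coding genes. TPM, the deposited length-corrected unit of abundance, reached 1 or more for 14843 genes in replicate 1 and 14876 in replicate 2, and for 14314 genes in both, 12637 of them protein-coding. Positions are 1-based on GRCm38, and levels are mean TPM ± SD with n = 2 unless a library is named.

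The epithelium of the distal lung was strongly represented. Sftpc, which encodes surfactant protein C and marks distal epithelium (ENSMUSG00000022097.3, chromosome 14 from 70520949 to 70524081), stood at 2155 ± 40.1 TPM. Of the 14 measured distal tip progenitor genes, 13 were detected in both libraries, with a median of 47.4 TPM, at percentile 99.8 of random protein-coding lists of the same size. Within that list Id2, an inhibitor of basic helix-loop-helix factors, reached 364 ± 10.1 TPM, the FGF target Etv5 185 ± 14.8 TPM and the receptor gene Fgfr2 150.4 ± 2.96 TPM, while the tip regulator Sox9 had 62.5 ± 2.10 TPM. The pan-lung epithelium list had 15 of 16 members detected and a median of 61.9 TPM, at percentile 100. Its leading members were the adhesion gene Epcam at 226 ± 0.544 TPM and the protease inhibitor gene Spint2 at 193 ± 15.6 TPM. Nkx2-1, the transcription factor of lung and thyroid identity (ENSMUSG00000001496.11, chromosome 12 from 56531958 to 56536908), had 75.6 ± 1.71 TPM, Foxa2 33.8 ± 1.38 TPM and Gata6 25.1 ± 0.834 TPM.

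Genes of the airway and alveolar lists were detected to different degrees. Sox2, the proximal airway factor, had 3.28 ± 0.608 TPM, far below Sox9. Of 12 proximal airway progenitor genes 10 were detected, with a median of 7.07 TPM, at percentile 62.6 of random lists. The secretoglobin gene Scgb3a2, an early airway marker, had 136 TPM in replicate 1 and 96.7 TPM in replicate 2. The alveolar type 1 list had 13 of 14 members detected with a median of 17.6 TPM, led by Igfbp2 at 268 ± 22.6 TPM and Cav1 at 264 ± 31.7 TPM, genes that other lung cells also express, and Ager at 55.4 ± 4.48 TPM. The alveolar type 2 list had 13 of 15 detected with a median of 9.20 TPM, at percentile 74.4 of random lists. It was led by Ctsh at 122 ± 23.2 TPM and Lyz2 at 97.9 ± 13.5 TPM, and which cells these came from was not tested. The mature airway lists had low medians, although some members stood higher. The club cell gene Scgb1a1 had 1 count in replicate 1 and 2 counts in replicate 2, both under the limit of 3 counts that a count of 0 allows. Of 10 club and goblet genes 2 were detected, Aldh1a7 at 89.1 ± 5.23 TPM and Cbr2 at 14.1 ± 2.69 TPM, and the list's median was 0.18 TPM. The ciliated cell list had 10 of 15 detected with a median of 1.87 TPM. It was led by Tubb4b at 479 ± 18.6 TPM, while the ciliary master regulator Foxj1 had 1.33 ± 0.424 TPM. The neuroendocrine list had 4 of 15 detected with a median of 0.44 TPM, led by Uchl1 at 43.7 ± 2.14 TPM.

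Mesenchyme, vessels and blood were all detected. The lung mesenchyme list had 21 of 22 members detected, with a median of 37.4 TPM. The mesenchymal factors Tcf21 and Foxf1 reached 184 ± 2.92 and 138 ± 10.3 TPM, and the lung field factors Tbx4 and Tbx5 56.4 ± 4.18 and 37.7 ± 2.29 TPM. All 24 extracellular matrix genes were detected, with a median of 107 TPM, led by the collagen gene Col3a1 at 1240.2 ± 25.3 TPM. All 14 smooth muscle genes were detected, with the actin gene Acta2 at 731 ± 4.89 TPM, and all 9 pericyte genes with a median of 7.03 TPM. Cartilage had 11 of 15 and mesothelium 9 of 11 members detected, with Col2a1 at 25.7 ± 3.77 TPM and Upk3b at 30.3 ± 2.05 TPM. All 20 blood vessel endothelium genes had a median of 50.01 TPM, led by Egfl7 at 232 ± 27.8 TPM, and all 7 lymphatic genes a median of 27.3 TPM, led by Ccl21a, which has near-identical copies. The erythroid list had 14 of 19 members detected, the platelet list 7 of 8, the macrophage list 13 of 15 and the list of other leukocytes 6 of 18. Among random lists, the pericyte, cartilage, mesothelium and macrophage medians stood at percentiles 62.2, 57.0, 63.8 and 66.8, and the platelet median at 41.3.

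The signalling genes of branching growth were detected in most cases. The FGF list had 17 of 18 members detected, the WNT list 24 of 27, the hedgehog list 14 of 15, the BMP and TGF-beta list 24 of 26, the Notch list 15 of 16 and the retinoic acid list 15 of 18. All 23 VEGF, PDGF and IGF ligand and receptor genes were detected. Among random lists, the FGF, WNT, hedgehog, Notch and retinoic acid medians stood at percentiles 83.1 to 92.0, and that of BMP and TGF-beta at 99.9. Fgf10, the mesenchymal ligand that drives bud outgrowth, had 14.5 ± 1.32 TPM. Shh had 4.79 ± 0.290 TPM and its receptor and target Ptch1 40.5 ± 1.99 TPM. Bmp4 had 41.0 ± 2.84 TPM, Wnt2 79.6 ± 3.48 TPM, Wnt7b 54.3 ± 7.13 TPM and Vegfa 5.54 ± 0.481 TPM. Of the Hox genes, 10 of 15 genes of groups 1 to 5, 4 of 8 of groups 6 to 8 and 0 of 16 of groups 9 to 13 were detected. Hoxb5 and Hoxa5 led the first of these with 56.6 ± 6.81 and 46.5 ± 0.962 TPM, and the median of groups 1 to 5 stood at percentile 43. Growth-related genes were high: all 36 proliferation genes were detected with a median of 142 TPM, led by Cdk1 at 546 ± 19.4 TPM, and 23 of 24 imprinted genes with a median of 108 TPM, led by Gnas at 1583 ± 49.2 and Mest at 1351 ± 14.9 TPM.

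Genes of neighbouring tissues were mostly low. The liver list had 4 of 18 members detected, the thymus list 3 of 10, the thyroid list 1 of 7, and the list of esophagus and stomach 1 of 11. The skeletal muscle list had 3 of 15 and the neural crest and glia list 9 of 16. The heart muscle list had 9 of 16, and its median was 9.86 TPM in replicate 1 and 1.71 TPM in replicate 2. Of the other lists, all 17 housekeeping, all 15 hypoxia and all 15 mitochondrial genes were detected, together with 17 of 20 immediate early and heat shock, 28 of 30 histone, 13 of 17 long non-coding and 5 of 15 small structured RNA genes. Histone and small structured RNA levels depend on how RNA without a poly(A) tail was captured, which is unknown here. Small structured RNA levels may also depend on the size minimum of 200 nt, and genes shorter than 100 nt could take no reads. In 36 of the 47 lists at least 50% of the measured members were detected. Random protein-coding lists of the same sizes had typical medians of 3.985 to 5.13 TPM. Detection of most members is therefore common among protein-coding genes and does not by itself show a programme. Levels of histone, globin and other near-identical copies are uncertain, because reads that fit several copies were split between them.

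**Figure D1:**
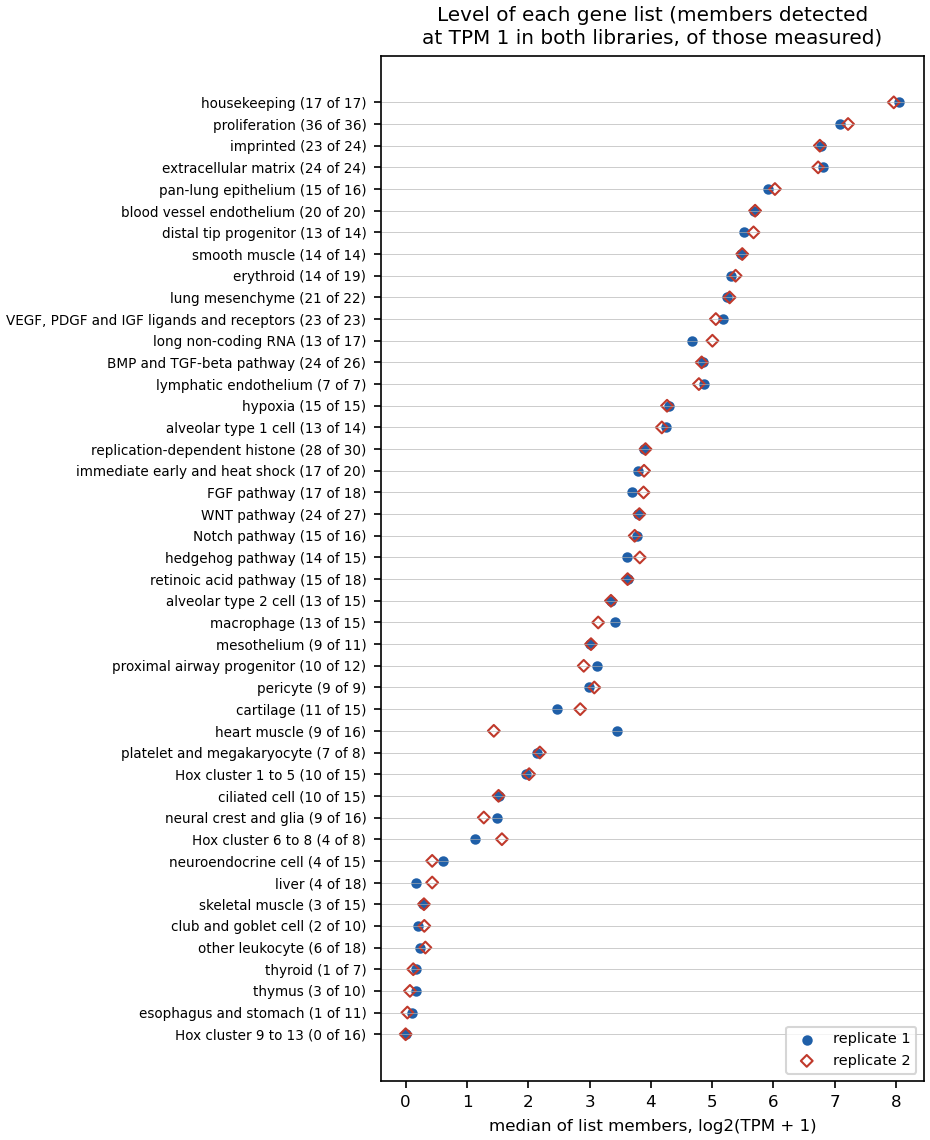
Median level of each gene list, in log2(TPM + 1), in replicate 1 (filled circles) and replicate 2 (open diamonds), with the number of members detected at TPM 1 in both libraries. The 2 libraries lie close together in most lists, and the heart muscle list stands apart with medians of 9.86 and 1.71 TPM.

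The composition of the libraries was similar for cellular RNA and differed for added RNA. Mitochondrial genes took 1.56 ± 0.0347% of the counts, ribosomal protein genes 2.93 ± 0.0306%, globin genes 0.748 ± 0.0113% and replication-dependent histone genes 0.158 ± 0.00272% (SD, n = 2). Spike-ins took 4.94% of the counts in replicate 1 (exact 95% interval 4.93 to 4.95) and 3.96% in replicate 2 (3.95 to 3.97). Among the highest genes outside the mitochondrial genome, the entry Gm42418, typed as long non-coding in the annotation used, stood at 11985 ± 380.2 TPM and Hba-a2 at 9745 ± 144 TPM. They were followed by the mitochondrial pseudogene Gm28437, Actb, the signal recognition particle RNA copies Rn7s1 and Rn7s2, Ppia, Eef1a1, Hist1h2ap and Hbb-bs, which had 4325 ± 19.4 TPM. Gm28437, Rn7s1, Rn7s2, Hist1h2ap and the globin genes share reads with near-identical sequences, so their separate levels are uncertain. The mitochondrial share above covers the mitochondrial genome only. Reads placed on Gm28437, annotated on chromosome 1, are outside that share, which may therefore be too low. Whether the reads on Gm42418 come from another kind of RNA was not tested.

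Embryonic globin chains made up a larger part of globin RNA in replicate 2. In the beta cluster, Hbb-y and Hbb-bh1 together took 12.4% of the counts in replicate 1 (exact 95% interval 12.2 to 12.6) and 15.97% in replicate 2 (15.8 to 16.2). In the alpha cluster, Hba-x took 1.87% (1.80 to 1.95) and 2.36% (2.28 to 2.44). The summed embryonic genes were 1.30-fold higher in replicate 2, a log2 ratio of 0.38 (0.35 to 0.41), and the 4 adult genes had a log2 ratio of -0.02 (-0.03 to -0.01). None of the 3 embryonic genes reached the 2-fold limit of the gene test.

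The replicates were close for most genes, and far apart for a small number. Across 14870 genes with mean TPM of 1 or more, Pearson's r on log2(TPM + 1) was 0.984 and Spearman's rho 0.987, computed across genes, which are not independent replicates. The biological coefficient of variation was 9.58%, and 97.4% of genes lay within 2-fold. Across 12864 protein-coding genes r was 0.992 and the coefficient 8.43%, and at mean TPM of 10 or more 99.9% of 8704 protein-coding genes lay within 2-fold. A chi-square test over 18733 genes gave a statistic of 148525 on 18732 degrees of freedom, with a p below the smallest number the software prints. Separate preparations of 1 RNA would also exceed counting noise, but would not differ as these libraries did in the 4 Y-linked genes below, with 7072 and 4 counts, and in Xist, with 18.54 and 27580, and the libraries were counted as 2 replicates.

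**Figure D2:**
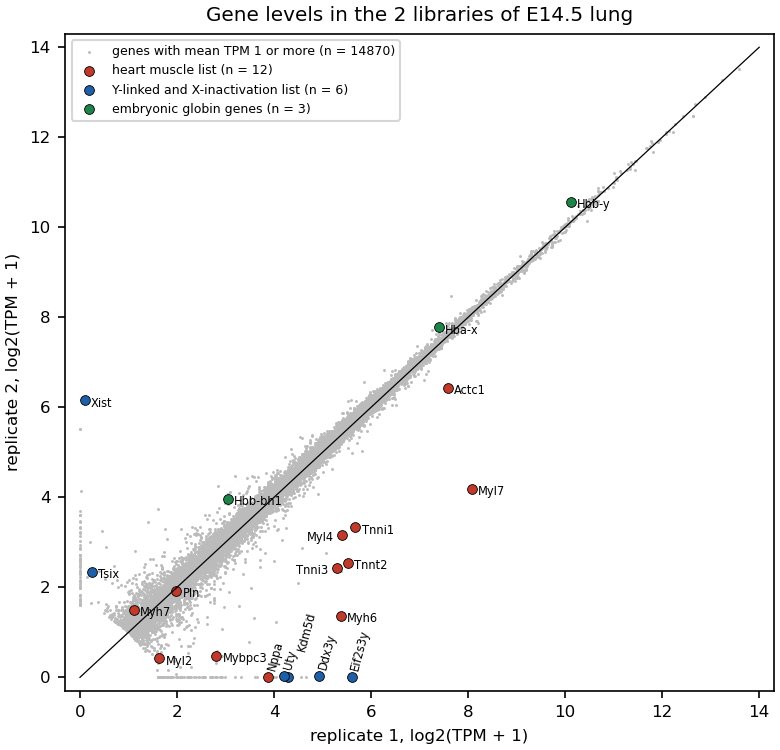
Level of each of 14870 genes in replicate 1 (x axis) and replicate 2 (y axis), both as log2(TPM + 1), with heart muscle, sex-linked and embryonic globin genes coloured and the line of equal levels drawn. Most genes lie along the line, while Xist lies above it and the Y-linked genes and most heart muscle genes lie below it.

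Between the libraries, 164 of 14870 genes differed by at least 2-fold at an adjusted p under 0.05 (exact binomial test, Benjamini-Hochberg), with 51 higher and 113 lower in replicate 2. Protein-coding genes accounted for 97 of these, 15 higher and 82 lower, and pseudogenes, which share reads with their parent genes, for 33, 16 higher and 17 lower. At any size, 3299 genes passed the adjusted p, and 2915 of them differed by less than 1.5-fold. Among called genes with a mean of at least 100 counts, 8 were higher and 36 lower in replicate 2. The higher ones included Xist, Tsix, the liver gene Afp (2.13-fold), the zinc finger gene Zfp473 (2.15-fold) and the processed pseudogenes Gm10254 (2.78-fold), Gm15429 (2.07-fold) and Gm10233. Gm10233 had 0 counts in replicate 1 and 211 in replicate 2, with deposited posterior SDs of 73.29 and 86.7 counts, so no fold is given. One entry without a symbol in the annotation used, ENSMUSG00000090234, had a rounded count of 0 in replicate 1 and 426 in replicate 2, and another, ENSMUSG00000090407, had 353 and 0, with posterior SDs of 68.93 to 88.44 counts for these values. In 138 of the 164 genes, 39 higher and 99 lower, the counts differed by more than 2 combined posterior SDs, a check chosen after seeing the data. With scaling by the spike-in sum, the median gene moved by 0.34 on the log2 scale and the count of genes differing between the libraries became 285, of which 70.2% were higher in replicate 2 against 31.1% with TMM. All directions below are relative to the median gene. With edgeR's exact test at the common dispersion of the same 2 libraries 106 genes were called, 22 of them higher in replicate 2, and all 106 were among the 164. Without the sex-linked, heart muscle and skeletal muscle lists, a setting chosen after seeing the data, 145 genes were called, 49 higher and 96 lower.

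Sex-linked transcripts separated the 2 libraries. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 113 TPM in replicate 1 and 0.05 TPM in replicate 2. Eif2s3y, a translation initiation factor gene (ENSMUSG00000069049.7, chromosome Y from 1010543 to 1028847), had 1557 counts in replicate 1 and 0 in replicate 2, at least 542-fold lower. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X from 103460366 to 103483254), had 0.07 TPM in replicate 1 and 70.1 TPM in replicate 2. Tsix, which overlaps Xist on the other strand, had 0.19 and 4.06 TPM, and without knowledge of strand its reads cannot be told from those of Xist. Zfy1, Zfy2, Usp9y and Sry had 0 counts in both libraries, which allows up to 0.0939 CPM of mouse gene counts in replicate 1 and 0.0905 in replicate 2. Of the 6 members tested, 2 were called higher and 4 lower in replicate 2, and the same numbers resulted when adjusted over the list alone. The labels describe both libraries as pooled male and female.

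Heart muscle genes were lower in replicate 2. Of 12 members tested, 10 fell in replicate 2, also when adjusted over the list alone, and the median log2 ratio was -2.93, at percentile 0 of 10000 random lists matched on expression. Myl7, the atrial myosin light chain (ENSMUSG00000020469.8, chromosome 11 from 5896637 to 5898782), had 270 TPM in replicate 1 and 17.3 TPM in replicate 2, which is 16.2-fold lower. Myh6, the alpha myosin heavy chain, was 23.4-fold lower, the myosin-binding protein gene Mybpc3 16.02-fold, the troponin gene Tnni1 5.68-fold and the cardiac actin gene Actc1 2.33-fold. Nppa, which encodes atrial natriuretic peptide, had 234 counts in replicate 1 and 0 in replicate 2, at least 81.4-fold lower. The Z-disc genes Actn2 and Csrp3, outside the list, were 20.7-fold and 17.0-fold lower. The 2 members that were not called, named after their values were seen, were Myh7 at 1.16 and 1.83 TPM and Pln at 2.97 and 2.78 TPM.

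**Figure D3:**
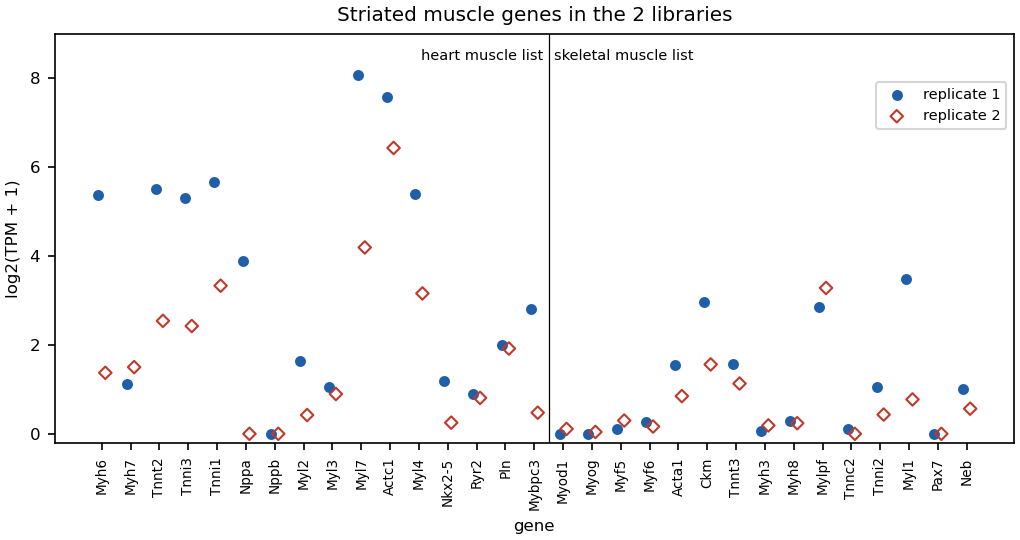
Level of each gene of the heart muscle list (left) and the skeletal muscle list (right), as log2(TPM + 1), in replicate 1 (filled circles) and replicate 2 (open diamonds). Myl7 had 270 and 17.3 TPM, while Myh7 and Pln lay close together in the 2 libraries.

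Of the 5 skeletal muscle genes tested, 3 fell in replicate 2, and 3 when adjusted over the list alone, with a median log2 ratio of -1.29 at percentile 0. These were the myosin light chain gene Myl1 (11.7-fold lower), the creatine kinase gene Ckm (3.597-fold) and the actin gene Acta1 (2.45-fold). Mylpf, a light chain of fast skeletal fibres, was not called, with 6.26 TPM in replicate 1 and 8.72 TPM in replicate 2. In the list of other leukocytes, 3 of 7 genes fell, and 3 when adjusted over the list alone, with a median of -0.62: the neutrophil genes S100a8 (5.82-fold lower) and S100a9 (7.38-fold) and the basophil protease gene Mcpt8 (4.61-fold). That list's percentile was 0.02, and without the filter on low values it was 27.8. Of the 6 liver genes tested, 2 rose in replicate 2, Afp and Apoa1 (2.45-fold), and 3 when adjusted over the list alone, with a median of 0.95 at percentile 99.99.

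Smaller shifts were found in further lists, and nearly all of their members stayed under the 2-fold limit. Of 41 lists with enough members, 13 lay outside the central 95% of random lists, 2 above and 11 below. Chance gives 2.05 if genes vary independently. Genes of 1 list may vary together, so the excess over 2.05 is not a test. The alveolar type 1 list had a median log2 ratio of -0.21 at percentile 0, with 10 of 13 members lower in replicate 2, such as Cav1 with 286 and 241 TPM. The alveolar type 2 list had a median of -0.19 at percentile 0.02, with 12 of 13 members lower, such as Ctsh with 138.5 and 106 TPM. Medians were -0.26 for pericytes, -0.22 for mesothelium, -0.11 for macrophages, -0.11 for mitochondrial genes and -0.10 for hypoxia genes. The proliferation list had a median of 0.02 at percentile 98.5, with 27 of 36 members higher in replicate 2. In these 8 lists 1 gene was called, the mesothelial gene Msln, at 2.98 TPM in replicate 1 and 1.24 TPM in replicate 2, and adjusting over the list alone left that number at 1. The pan-lung epithelium, distal tip, lung mesenchyme, vessel endothelium and erythroid lists and all lists of signalling pathways lay within that range and held no called gene. Single called genes in other lists, named after their values were seen, included Prph with 53 and 27 counts in the neural crest and glia list, Snora73b with 1 and 15 counts among small structured RNAs, and Xist, which the long non-coding list also holds.

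**Figure D4:**
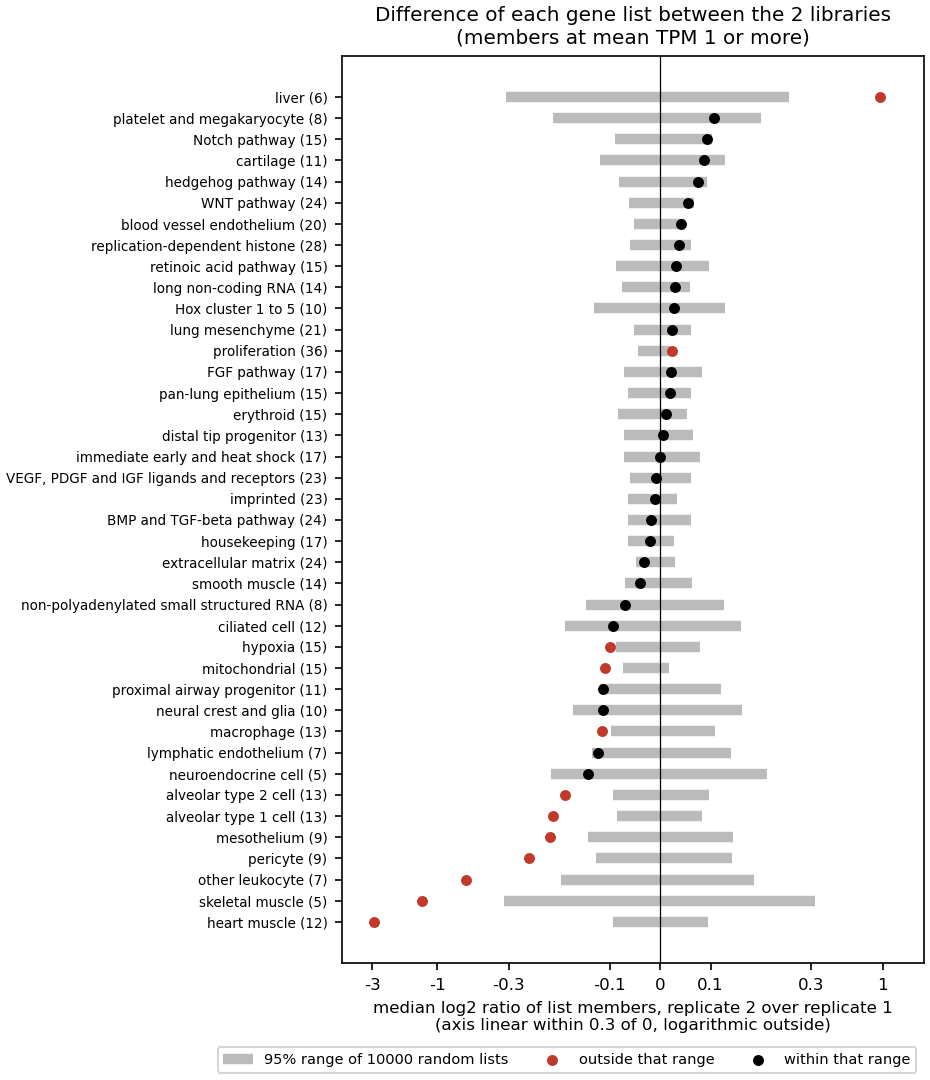
Median log2 ratio of replicate 2 over replicate 1 for each gene list (points) with the 95% range of 10000 random lists matched on expression (grey bars), on an axis that is linear near 0 and logarithmic outside. The heart muscle list lies lowest at -2.93 and the liver list highest at 0.95; the Y-linked and X-inactivation list is not drawn.

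The most abundant transcript was the same in both libraries for most genes. Among 7936 genes with several transcripts and mean TPM of 5 or more, it was the same one in 7384, or 93.0% (exact 95% interval 92.5 to 93.6). Pkm, the pyruvate kinase gene, carried 95.2 ± 0.335% of its TPM on the transcript with the downstream exon of its exclusive pair (chromosome 9 from 59675568 to 59675734), the exon of the M2 form. Nkx2-1 carried 89.5 ± 2.23% on its main transcript of 2242 nt. In Fgfr2, transcripts with the upstream exon of the pair that sets ligand binding (IIIb, chromosome 7 from 130199758 to 130199905) took 71.4 ± 2.08% of the TPM of transcripts with either exon, and those with the downstream exon (IIIc, 130198419 to 130198563) 28.6 ± 2.08%. Transcripts with either Fgfr2 exon held 41.8 and 15.6 TPM in replicate 1, and the rest of the gene's 148 TPM lay on annotated transcripts with neither. In Fgfr3 the upstream exon took 52.8 ± 0.235%.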

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

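The test of a shared pool for the sex-linked genes below was chosen only after the result was seen, while the test on genes that escape X inactivation was written before its values were looked up. Features with a numeric identifier, which no comparison used, held 50 expected counts in replicate 1 and 47.64 in replicate 2, summed over all of them. The limit of 3 counts that a count of 0 allows holds for a single feature, so these sums cannot be set against it. With no control samples there was no other limit to compare with, and what these features represent was not tested.

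Y-linked genes were found almost wholly in replicate 1 and Xist in replicate 2, although the labels call both libraries pooled male and female. Pools of both sexes would leave both kinds of RNA in each library, but the larger of the 2 remainders, that of Xist in replicate 1, was 0.0998% of its level in replicate 2, which argues against such pools. Tissue of a male embryo in replicate 1 and of a female embryo in replicate 2 is a candidate explanation, and it predicts higher levels of genes that escape X inactivation in replicate 2. The 5 genes listed for this, Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Pbdc1, had a median log2 ratio of 0.52, with 5 of 5 higher, at percentile 100 of random lists, while 518 other X-linked genes had a median of -0.03 at percentile 0.03. The labels also give each sample as pup 1, an exchange of a sample with one outside the series was not tested, and the design, with 1 group, gives no biological explanation to test.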

How the results depend on the processing

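The alternatives restricted to protein-coding genes, to count differences above 2 posterior SDs, without the sex-linked and muscle lists, and leaving out each replicate for transcript classes and globin shares, and the sums of sex-linked genes, were chosen after seeing the data; the cause of a change was not tested unless the setting itself gives it. No paired analysis was possible because the series holds 1 group. No called value changed direction. Genes at TPM 1 or more in both libraries (14314) ranged from 10765 to 16483 over the detection thresholds, and 13 of 41 lists lay outside the random range, or 10 of 33 at mean TPM of 5 or more. For replicate agreement, r was 0.958 with a pseudocount of 0.1, 0.994 without a filter on TPM, 0.987 at mean TPM of 10 or more and 0.995 at 10 or more counts in both libraries. The median log2 ratio was 0.00655 with total counts and 0.34 with spike-ins. For genes differing between the libraries, with 164 called (51 higher and 113 lower in replicate 2), spike-in scaling gave 285 with 200 higher, no filter 477 (164 higher, 313 lower), 10 or more counts in sum 479 (175 and 304), a 1.5-fold limit 384 (140 and 244), a 4-fold limit 79 (19 and 60), edgeR's exact test 106 with 22 higher, and protein-coding genes alone 98 with 16 higher. Without the sex-linked and muscle lists 145 were called, 49 higher and 96 lower, and with the limit on posterior SDs 138. As shares of TPM, mitochondrial genes took 2.88%, globin genes 2.27%, ribosomal protein genes 7.44%, histone genes 0.608% and spike-ins 9.86%, and the embryonic share of the alpha cluster was 1.42%, since TPM weights short transcripts more. The share of genes with the same leading transcript was 90.6% at mean TPM of 1 or more and 94.8% at 20 or more. By posterior mean TPM, which gives features without reads a value above 0, the remainder of Y-linked RNA in replicate 2 was 0.982% and that of Xist in replicate 1 0.507%. Without the filter the proximal airway list moved outside the random range (percentile 0.24) and the other leukocytes inside it (27.8). Of 236 named genes, rescaled TPM moved 163, all upward, and posterior mean TPM moved 59. With 2 replicates, leaving 1 out always shifts a mean by less than 1 SD, so for named genes, transcript shares and classes this setting says nothing about stability; spike-ins ranged from 3.96 to 4.94% and the embryonic share of the beta cluster from 12.4 to 15.97%. Of 47 list medians, rescaled TPM moved 32, posterior mean TPM 21, and leaving out replicate 1 or 2 moved 11 or 8. Of 24 transcript shares, posterior means moved 9. Depth limits genes near 3 counts.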

Other observations

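The tests of ventricular muscle, of skeletal muscle (after 2 other sums of its genes had been seen) and of more blood below were chosen only after the result was seen; the tests of atrial-type muscle and of maturity used lists written before their values were looked up, but both hypotheses were formed after related shifts had been seen.

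Further genes of striated muscle and myeloid cells were called lower in replicate 2, and those named here were chosen after their values were seen. Ttn, which encodes the giant sarcomere protein titin, had 2109 counts in replicate 1 and 190 in replicate 2, and the slow and cardiac troponin gene Tnnc1 had 561 and 57. Sln, which encodes sarcolipin and is typical of atrial muscle, had 146 and 3 counts. The neutrophil granule gene Ngp had 67 and 7 counts.

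Heart muscle genes were higher in replicate 1 in a pattern that leaned to the atrial forms. Ventricular muscle carried over in dissection would bring Myl2, Myl3 and Myh7, but their summed excess in replicate 1 was 0.511% of that of Myl7, although Myl2 itself fell, from 15 counts to 3. The 5 tested members of the skeletal muscle list summed to 27.19 TPM in replicate 1 and 13.37 in replicate 2, a ratio of 2.03. For Acta1, Mylpf and Tnnt3 alone the sums were 10.15 and 10.71 TPM, a ratio of 0.948. The excess of the 5 members was 5.47% of that of Myl7 (counting error 0.658), which argues against skeletal muscle as the source of the whole pattern. This percentage does not measure a skeletal share, so whether a part of the pattern came from skeletal muscle is left open. More atrial-type muscle, from the heart or from the muscle sleeve of pulmonary veins, is a candidate explanation. Of a second list of 25 heart genes, the 13 with mean TPM of 1 or more had a median log2 ratio of -0.77, at percentile 0. All of these, 13 of 13, were lower in replicate 2. That list covers heart muscle of any kind, so it cannot show that the muscle was atrial. Some members, such as Tcap at 2.96 and 0.05 TPM, passed the filter only through replicate 1. Atrial markers do not decide the question. Of 14 atrial genes other than Myl7, Myl4 and Nppa, the 7 that passed this filter, among them Sln, had a median of -0.10 at percentile 12.7. Others of them, such as Clu at 233.9 and 221.8 TPM, stood at a high level in both libraries. Atrial-type muscle from dissection and a difference between embryos therefore cannot be told apart.

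Embryonic globin genes were higher in replicate 2. More blood of every kind would raise adult globins alike, but the log2 ratio of embryonic globins exceeded that of adult globins by 0.41. A less mature embryo in replicate 2 is a candidate explanation: of 27 genes listed as rising through lung maturation 24 passed the filter and 20 were lower in replicate 2, with a median log2 ratio of -0.15 at percentile 0, and of 9 listed as falling, all of which passed, 8 were higher, with a median of 0.10 at percentile 97.9. These shifts are small, the alveolar and proliferation lists had already moved the same way, and collection day, embryo and sex-linked RNA differ together between the 2 libraries, so no biological explanation from the design was tested.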
